A study of Mus with 6 samples.

How the data were processed

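Hippocampal total RNA of 3 male mice in each of 2 groups was copied to cRNA, labelled with the dye Cy3 and hybridised to 1-colour arrays, per the labels. The labels give the group and the replicate number of each array. They say that RNA came from 3 mice in each group, but not in so many words that each array holds 1 mouse, so the p-values measure the spread between these 6 samples. Arrays were read out with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes.

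The deposited table holds 1 value per probe and array for 166924 probes, with none missing. The values were taken as log2 signal because the deposited columns run from 0.79 to 19.2, and neither the log base nor the background correction is given in the sources used here. The sorted values of the 6 columns differed by at most 0.026 at any rank, as after quantile normalization by the authors, so a shift of all transcripts on an array cannot be seen. No detection flags, background or spot counts were used here. The floor of 1.5 is the upper edge of the emptiest 0.25-wide bin between the pile of lowest values and the rest, and it held 12857 or 12858 probes on each array. A probe at or below it on every array of a group has only a bound there, and its fold is given as "at least", from the mean of the other group against the floor.

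The values were used as deposited, with no filter, since the arrays already share a distribution. Each probe was fitted with group as the only term (limma 3.58.1 in R 4.3.3, eBayes with a trend over mean signal, prior degrees of freedom 1.95) and p-values were adjusted by Benjamini-Hochberg over all probes. Differences are TG minus NS. A screening threshold of 2-fold with an unadjusted p under 0.05 was used beside the adjusted threshold of 0.05. Single values were compared by exact permutation tests, which cannot go below p = 0.1 with 3 arrays against 3, and classes of probes by Fisher's exact test. Principal components were taken over all probes, centred and not scaled. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

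The probes named in the text are 2 that rose and 2 that fell, picked by a rule fixed before the data were examined. Probes past the adjusted threshold with no overlap between the groups come first by size. Remaining places are filled, in order of p, by probes with an unadjusted p under 0.05, a difference of at least 2-fold, no overlap and a mean above the median probe. Places filled by p need not hold the largest differences. The files do not pair probe IDs with genes, so the gene lists fixed for brain cell types and pathways, the check of sex-linked and housekeeping genes and the choice of 1 probe per gene were not run. The RNA class of a probe was read from its name alone. The comparisons of single arrays and pairs of arrays were added after the data were seen. The plan also held neither the count of probes at least 4-fold apart between the groups nor the tests of how often each RNA class was called.

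The fit was tested on simulated arrays for the comparison of TG with NS, with 200 of 166924 probes, all brighter than the median, changed by a known fold in each of 5 runs. At the adjusted threshold 20.8% of 2-fold changes, 61.6% of 4-fold changes, 88.4% of 8-fold changes and 88.8% of 16-fold changes were recovered. At the screening threshold these shares were 46.8%, 98.4%, 100% and 99.6%, and a mean of 1805.2 unchanged probes per run also met it. A mean of 4 unchanged probes per run passed the adjusted threshold. The noise was drawn independently for each probe, without variation shared by the probes of an array. With 200 changed probes the adjusted cutoff is also looser than where 1 probe passes. The shares at the adjusted threshold may therefore be too high for the real arrays. Alternatives tried were other scalings between arrays, a mild and a strict filter on dim probes (the 125193 or the 83462 probes with the highest mean over all arrays), other variance models, array weights, the replicate number as a block, and leaving out each array in turn.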

Results

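RNA from the hippocampus of male mice with an Alzheimer's disease (AD) model, made by giving the amyloid-beta fragment Aβ25-35, was measured on 6 arrays. The model mice had received either 0.9% saline at 0.5 ml per day (NS, 3 mice) or Tripterygium glycoside at 0.25 mg per 10 g of body weight per day (TG, 3 mice). Tripterygium glycoside is an extract of the vine Tripterygium wilfordii that is used against inflammation. The series concerns long noncoding RNA (lncRNA) and circular RNA (circRNA), the latter being RNA loops closed by back-splicing. Each array gave a log2 signal for 166924 probes. Probe names beginning with MMU_CIRCpedia (11024 probes) or mmu_circ (4297 probes) refer to circRNA, 15321 probes or 9.18% of the total. The other 151603 probe names begin with mclstr, and the files pair neither these with a gene nor say which of them read mRNA and which lncRNA. The median signal was 6.09 on each array, and 7.70% of the values on each lay at or below 1.5, taken here as the floor of the signal. Array data carry no read depth, so the number of arrays limits the precision.

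The first comparison asked which transcripts of the AD hippocampus differed after TG. The signal of mclstr_53594_1667_6 rose from the floor on all 3 NS arrays to a clear level on all 3 TG arrays. Its log2 signal was 1.07 ± 0.26 in NS and 9.14 ± 0.33 in TG (SD, n = 3 each). Against the floor this is a rise of at least 200-fold, and it was the only probe past an adjusted p of 0.05 (limma, adjusted p = 0.00879). The call was lost when any 1 of NS replicates 1 and 3 and TG replicates 1 and 3 was left out. The call was also lost with an unmoderated statistic (adjusted p = 0.290, limma without eBayes). With the replicate number as a block it was lost too (limma adjusted p = 0.211). Over all settings the adjusted p of this probe ran from 4.52e-04 to 0.290.

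The next probes missed the adjusted threshold, and their groups did not overlap. For mclstr_42376_839_14 the log2 signal was 11.16 ± 0.47 in NS and 5.97 ± 0.06 in TG (SD, n = 3 each), a difference of -5.19 ± 0.23 (SE, 36.5-fold lower in TG, limma adjusted p = 0.0513). For mclstr_55753_1160_16 it was 11.63 ± 0.50 in NS and 7.23 ± 0.12 in TG, a difference of -4.40 ± 0.25 (SE, 21.1-fold lower in TG, limma adjusted p = 0.138). For mclstr_25317_1462_7 it was 7.13 ± 0.03 in NS and 9.00 ± 0.21 in TG, a difference of 1.87 ± 0.13 (SE, 3.66-fold higher in TG, limma adjusted p = 0.138). In other settings, chiefly filters on dim probes, robust eBayes or leaving out NS replicate 2, mclstr_42376_839_14 passed the adjusted threshold in 5 of 17, mclstr_55753_1160_16 in 4 and mclstr_25317_1462_7 in 2. Over all settings their lowest limma adjusted p was 0.00418, 0.0140 and 0.0313, and the highest was 0.524 for each. The exact permutation test gave p = 0.1 for each of the 4 probes (two-sided), the smallest value that 3 arrays against 3 allow.

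**Figure D1:**
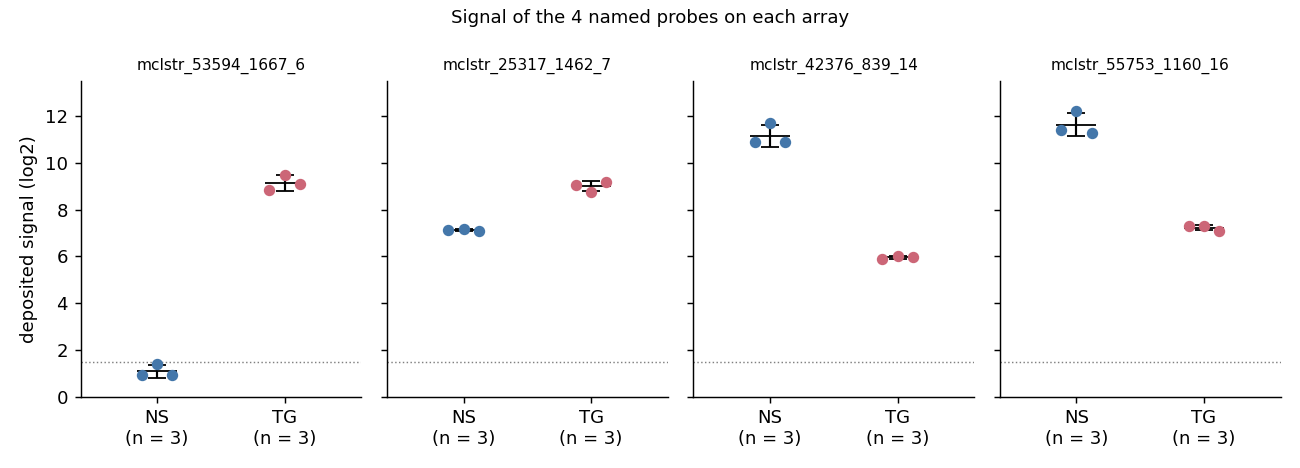
Deposited log2 signal of the 4 named probes on each of the 6 arrays, with 1 point per array and the mean ± SD of each group of 3 (bars). The dotted line marks the floor of 1.5, under which all 3 NS values of mclstr_53594_1667_6 lie.

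In 33 probes every TG array was at least 4-fold away from every NS array, 20 of them higher and 13 lower in TG. The other ways to part the 6 arrays into 3 and 3 gave at most 19 such probes, and the median over all 10 ways was 5.5. None of these was a circRNA probe. Among the lower ones, 6 were brighter than the median probe, and their mean log2 differences ran from -5.19 to -3.10.

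At a looser screening threshold, a difference of at least 2-fold with an unadjusted p under 0.05, 3423 probes were called. Of these, 2069 (60.4%) were higher and 1354 lower in TG, and 309 differed by at least 4-fold. With 1 array left out, the share higher in TG ran from 50.4% (without TG replicate 3) to 63.6% (without NS replicate 1). Without TG replicate 1 it was 53.8%, so the excess of rises depended on single arrays. Most calls came from dim probes: 1011 (29.5%) were brighter than the median probe, and 740 had a group mean at or below the floor. On unadjusted p alone, 15667 probes lay under 0.05, 8674 of them higher and 6993 lower in TG. The nominal chance count is 8346.2, and the same fit on simulated arrays gave a mean of 9145.4 among unchanged probes. Parting the arrays as NS replicate 1 with TG replicates 1 and 3 against the rest, a split that mixes the treatments, gave 14177. The groups did not overlap in 27127 probes (16.3%), against 10% by chance. Without TG replicate 2 the screening count was 5962 and the count past the adjusted threshold 20. When only the 125193 probes with the highest mean signal were tested, these counts were 1825 and 12.

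CircRNA was compared with the mclstr probes because the series is about it. No circRNA probe passed the adjusted threshold (limma, smallest adjusted p = 0.242), while 1843 had an unadjusted p under 0.05, 740 of them higher and 1103 lower in TG. The screening threshold was met by 131 circRNA probes, 66 higher and 65 lower in TG, of which 86 carried the MMU_CIRCpedia and 45 the mmu_circ prefix. Without TG replicate 2 that count was 333. The median absolute log2 difference of these calls, which the threshold holds to at least 1, was 1.21, against 1.29 for the mclstr calls. Among the circRNA calls 8 differed by at least 4-fold, and the extremes were 2.45 and -3.20. Over all circRNA probes the array median was 8.35 ± 0.013 in NS and 8.31 ± 0.049 in TG on the log2 scale (SD, n = 3 each). That difference of -0.037 gave an exact permutation p of 0.3 (two-sided).

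CircRNA probes met the screening threshold less often than mclstr probes. The share was 0.855% of circRNA probes (95% exact interval 0.715 to 1.01) against 2.17% of mclstr probes (2.10 to 2.25), an odds ratio of 0.389 (Fisher's exact test, p = 2.45e-34). On the unadjusted p alone the order was the opposite, 12.03% of circRNA probes against 9.12% of mclstr probes (odds ratio 1.36, Fisher's exact test, p = 5.78e-30). CircRNA probes were brighter, with a median log2 signal of 8.33 against 5.83, and the median standard error of their log2 difference was 0.14 against 0.22. The calls also differed in direction, since 2003 of 3292 mclstr calls were higher in TG. The odds ratio of a higher call for circRNA was 0.654 (95% interval 0.453 to 0.942, Fisher's exact test, p = 0.0178). The odds ratio was lower when dim probes were left out, 0.476 among the 125193 probes with the highest mean signal (Fisher's exact p = 4.78e-04) and 0.293 among the top 83462 (Fisher's exact p = 7.48e-06). On unadjusted p alone it was 0.498 (Fisher's exact p = 3.67e-44). The direction test missed 0.05 after cyclic loess (odds ratio 0.723, Fisher's exact p = 0.0758), with an unmoderated statistic (0.791) and when any 1 array other than TG replicate 2 was left out (0.686 without TG replicate 3 to 0.979 without NS replicate 2). It also missed 0.05 with the replicate number as a block (odds ratio 0.712, Fisher's exact p = 0.0634). Probes are not independent of each other, so these tests across probes overstate their certainty.

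The last comparison asked whether the arrays of a group resembled each other. The mean correlation across probes was 0.982 within NS, 0.980 within TG and 0.979 between the groups, and the difference of 0.00221 between pairs within and across groups gave an exact permutation p of 0.1 (one-sided), the smallest this design allows. The highest correlation of all pairs was between the groups, 0.9831 for NS replicate 2 with TG replicate 2. TG replicate 2 correlated at 0.9826 with NS replicate 1 and 0.9808 with NS replicate 3. With TG replicates 1 and 3 it correlated at 0.9808 and 0.9788. TG replicates 1 and 3 correlated at 0.9802 with each other, and TG replicate 1 at 0.9807 with NS replicate 1. The first principal component held 29.4% of the variance and the second 21.0%. On the first, TG replicates 1 and 3 scored 127 and 114, TG replicate 2 scored -14.5, and the NS arrays scored -34.8, -64.1 and -128 (exact permutation test of TG against NS, two-sided, p = 0.1). On the second, TG replicates 1 and 3 lay far apart, at 93.3 and -141.

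**Figure D2:**
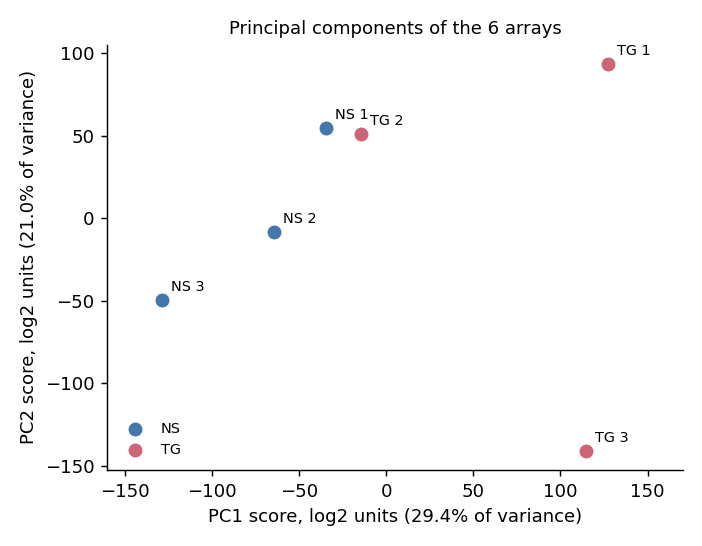
Scores of the 6 arrays on the first principal component (x axis, 29.4% of variance) and the second (y axis, 21.0%), in log2 units, with NS and TG in different colours. TG 2 (-14.5 on the x axis) lies nearest to NS 1 (-34.8), while TG 1 (127) and TG 3 (114) lie apart from the rest. TG 1 and TG 3 also lie far from each other on the y axis (93.3 and -141).

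TG replicates 1 and 3 shared high signals that TG replicate 2 did not reach. In 104 probes, 2 of them circRNA, both arrays were at least 4-fold above each of the other 4. The median log2 signal of these probes was 8.07 on TG replicate 1 and 7.77 on TG replicate 3, against 4.39 on TG replicate 2 and 4.40, 3.92 and 3.97 on the NS arrays. Another 16 probes were at least 4-fold lower on both. The 120 probes compare with at most 25, and a median of 13, for the other ways to pick a pair from the 6 arrays. Of the 104 probes, 70 are among the screening calls of TG against NS and 0 among the adjusted calls.

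**Figure D3:**
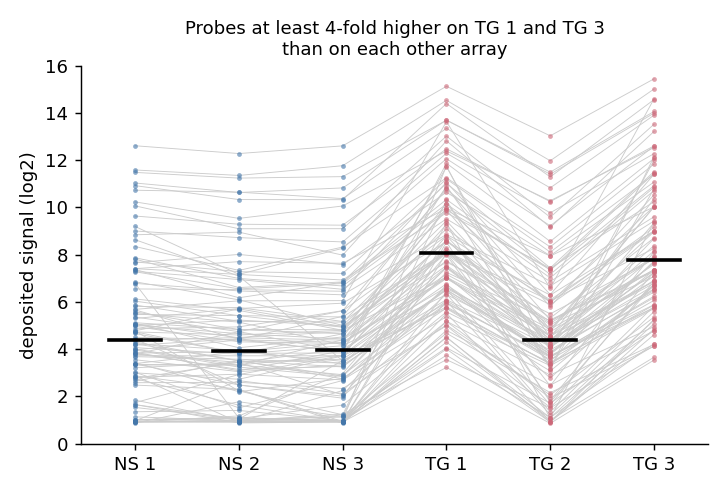
Deposited log2 signal (y axis) on each of the 6 arrays (x axis) of the 104 probes at least 4-fold higher on TG 1 and TG 3 than on each other array, with 1 grey line per probe and the median of each array as a black bar. The medians are 8.07 on TG 1 and 7.77 on TG 3, and between 3.92 and 4.40 on the other arrays.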

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

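The settings for the circRNA median and the spread between arrays, and those of the class results other than the dim-probe filters, were chosen after the data were seen. Quantile normalization again, centring on the median or the 75th percentile, no trend and array weights left the count at adjusted p under 0.05 at 1. It was 2 after cyclic loess, 12 and 11 with the mild and the strict filter on dim probes (125193 and 83462 probes left), 4 with robust eBayes, 0 unmoderated and 0 with the replicate block. Without 1 array it ran from 0 (NS 1, NS 3, TG 1, TG 3) to 20 (TG 2), with 5 without NS 2. The screening count was 1825 and 1120 with the mild and the strict filter, 2010 unmoderated, and 3069 to 5962 (without TG 2) with 1 array left out. The circRNA screening count was 59 with the strict filter, 80 unmoderated, and 94 to 333 (without TG 2). The odds ratio of direction was 0.476 and 0.293 with the mild and the strict filter, both past 0.05. It was 0.723 after cyclic loess, 0.791 unmoderated, 0.712 with the replicate block, none of them past 0.05, and 0.436 to 0.979 with 1 array left out, past 0.05 there only without TG 2. The causes of these shifts between settings were not tested. The 4 named probes kept their direction in all settings. Adjusted p of mclstr_53594_1667_6 ran from 4.52e-04 to 0.290 (0.211 with the block), with its call lost in 6 of 16 settings, the block and the unmoderated statistic among them, and the strict filter removed it. Residual correlations between arrays of the same replicate number were 0.149, 0.0186 and 0.0333. For 2 NS arrays the best TG match was their own number, so a pairing by replicate number was neither shown nor excluded. The circRNA median difference ran from -0.060 to -0.011. Gene lists, 1 probe per gene and single control genes were not run, for want of gene names. With no background values, signal over background is unknown.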

Other observations

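Except for the splits of the circRNA calls and the main test of brightness for circRNA, the tests in this part were chosen after the results were seen. The lower share of circRNA calls that the brightness test addresses was itself outside the plan. The odds ratios within bins for the other splits and for unadjusted p were additions to that test.

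The 6 bright probes that were at least 4-fold lower on every TG array than on every NS array moved together within the NS group as well. Their signal above the TG mean was 1.80-fold higher on NS replicate 2 than on NS replicate 1, and the SD of that log2 ratio across the 6 probes was 0.0332, or 0.0941 of the smallest SD between NS arrays over probes of matched brightness (0.353). For NS replicate 3 against NS replicate 1 the mean log2 ratio was -0.13, with an SD of 0.0862 (0.243 of the matched SD), and against NS replicate 2 the SD was 0.0865 (0.245). The hypothesis that these probes read 1 RNA source, a single transcript or a set regulated as a unit, passed a test that a ratio of spreads of 1 or more would have failed. mclstr_42376_839_14 and mclstr_55753_1160_16 belong to them, so the 2 named falls may be 1 event and not 2, and a genotype or dissection difference that follows the groups was not tested.

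The shared high signals of TG replicates 1 and 3 were set against a TG response of like size in all 3 mice, by choosing 192 probes at least 4-fold higher on TG replicates 1 and 3 than on every NS array without regard to TG replicate 2. The 192 probes hold the 104 described above, and over all of them the median log2 rise of TG replicate 2 was 0.72, under the bound of 1.53 by more than the 0.41 between NS arrays, although it lay above every NS array in 138 (71.9%). Chosen in the same way, 37 probes gave TG replicate 1 a median rise of 2.57 and 29 gave TG replicate 3 a rise of 3.37. Each set holds the 20 probes at least 4-fold higher on every TG array. They make up most of the 37 and of the 29 but few of the 192. Both of these medians were therefore bound to be high and are no free comparison for TG replicate 2. In the 192 probes the measured rise was thus not of like size in all 3 mice. The 104 probes among them had been picked with TG replicate 2 low, so this result largely restates that pattern and is no independent evidence. For a wrong label of TG replicate 2, joining it to TG replicates 1 and 3 parted 33 probes by at least 4-fold. With NS replicate 1, 2 or 3 in its place 19, 2 and 9 were parted, but 4 arrays are too few to exclude a wrong label. Against the label, TG replicate 2 correlated more closely with NS replicates 1 and 2 than with TG replicates 1 and 3. TG replicate 1, however, also correlated more closely with NS replicate 1 (0.9807) than with TG replicate 3 (0.9802). These correlations therefore cannot settle the label. On TG replicate 2 the log2 signal of mclstr_53594_1667_6 was 9.50 against at most 1.37 in NS. That probe was chosen by the labels, so its values cannot test them. Also open is 1 added tissue or RNA source in fixed proportions. The spread was 1.40 times that between NS arrays, or 1.01 if brightness is matched over all 6 arrays. The bound for this spread, first 1.5, was tightened to 1 after the value was seen. A weaker response or dosing of 1 mouse or a dissection difference is open too and was untested. Any of these may give this pattern. A shared trend along the first number of the mclstr names had no support. Its correlations over bright probes ran in opposite directions (-0.143 on TG replicate 1 and 0.106 on TG replicate 3, product -0.0151). Only that of TG replicate 1 was larger in size than on every NS array (0.125 on NS replicate 2), so a trend was not excluded.

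The lower share of circRNA probes at the screening threshold was set against their higher brightness. Within 20 bins of brightness the odds ratio of a call was 0.582 (95% interval 0.488 to 0.695), so brightness alone does not account for it. Within the same bins, the other splits of the 6 arrays into 3 and 3 gave odds ratios from 0.416 to 0.836. The lower share therefore goes with the probes whether or not the arrays are parted by TG. On unadjusted p alone, the odds ratio within these bins was 1.08 (1.02 to 1.14). A smaller spread of circRNA signals between arrays stays open as a reason, as does the unstated background correction.

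The 6 arrays can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The split by treatment gave 3423 screening calls, with 2811 as the highest of the other splits, 131 circRNA calls, with 84 as the highest other, and 15667 probes with an unadjusted p under 0.05, with 14177 as the highest other, so 1 of 10 splits reached the real value in each case. At the adjusted threshold it gave 1 call, the highest other gave 3, and 4 of 10 splits gave at least 1. The highest other in all of these was the split of NS replicate 1 with TG replicates 1 and 3 from the rest.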
